A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

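The libraries are amplicons of integrated sgRNA sequences from genomic DNA of sorted or unsorted cells, and of 3 plasmid pools. As deposited, the values of all 5 tables are raw read counts per sgRNA: whole numbers that the authors did not scale, with a different total in each library. Per the submitters' processing notes MAGeCK was used for all libraries but the 4 THP-1 genome-wide ones; its role and version are not given in the sources used here. All 27 libraries were used, no value column was left out, and nothing was realigned. The genome-wide human table holds 209070 sgRNAs (3790 non-targeting) for 18903 genes, the mouse one has 107415 (2170 non-targeting) for 20001 genes, and the sublibrary has 16761 (490 non-targeting) for 1578 genes. In the sublibrary 319 empty cells in 194 sgRNAs were taken as 0, since that table prints no 0. "Up" and "down" of the THP-1 table were read as the top and bottom 25% of CD11b, which the counts of ITGAM sgRNAs bear out. The libraries titled day 6 carry the name day 0 in the mouse table and were kept as the unsorted reference.

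Counts were fitted per sgRNA with edgeR 4.0.16 in R 4.3.3, after TMM scaling, by the quasi-likelihood F-test. The THP-1 fit used its 4 libraries, with 2 residual degrees of freedom and a common biological coefficient of variation of 0.274. The ER-Hoxa9 fit used its 10 libraries in 5 groups, with 5 residual degrees of freedom and a coefficient of 0.171. An sgRNA needed a mean count of at least 20 over the libraries fitted, which kept 197884 human and 93787 mouse sgRNAs. Each test was turned into a signed z. A gene's statistic was the mean z over at least 3 sgRNAs minus the mean of non-targeting sgRNAs. Its two-sided permutation p came from 100000 draws of as many non-targeting sgRNAs, and was adjusted over genes after Benjamini and Hochberg. A gene passed with an adjusted p under 0.05 and the same sign of its mean log2 ratio in both replicates. At the sgRNA level 1018 sgRNAs passed in THP-1, 2 of them among 3608 non-targeting ones, and 52 in the ER-Hoxa9 CD11b screen, none among 1971. The median SE of a gene's log2 ratio was 0.159 in THP-1, 0.140 in the ER-Hoxa9 CD11b screen and 0.128 in the GFP screen. The shallowest library is CD11b-low replicate 1 of ER-Hoxa9, with a median of 27 reads per sgRNA.

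Comparisons were CD11b up against down in THP-1, CD11b high against low and GFP high against low in ER-Hoxa9, the difference of those 2, and the mean of the 4 sorted day 8 groups against day 6. The replicate numbers pair the fractions, since the protocol starts replicates at infection. Deviations of paired fractions from their group means correlated at 0.148 in THP-1. Over 10 pairs of ER-Hoxa9 groups they correlated at 0.0991 to 0.132 between day 8 fractions. Between these and day 6 they correlated at -0.0034 to 0.0032. The models carried no replicate term, and a fit with the replicate block was run beside each. With 2 libraries per group no other splits of the samples were counted.

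Sublibrary screens and plasmid pools have 1 library per group and were not tested. A gene's value there is the mean over sgRNAs of the log2 ratio of library totals-scaled counts with 1 count added, centred on the median of non-targeting sgRNAs. The human plasmid pools were each used for the sgRNAs they hold, which left out 14381 sgRNAs in neither pool.

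Of 41 gene lists, 40 were tested for each comparison, and the list of sorted markers served as a check of labels. A list's mean z was set against 10000 random lists of its size (two-sided permutation over genes), adjusted over the 40 lists, and against lists matched on mean sgRNA count. Numbers of members that passed are given over all genes tested, and for part of the lists also adjusted over the list alone. List means were also compared between THP-1 and ER-Hoxa9, each scaled by the screen's spread, by permutation over genes. Symbols were matched without regard to case, older symbols included. Positions are those of GENCODE v44 on hg38, in which 17533 of 18903 human genes were found by symbol. Only 11.2% of 190590 positions written in human sgRNA names lie within 5000 bp of the hg38 gene, so sgRNA positions are not given, and no mouse positions are given. Genes sharing sgRNAs with another gene number 767 in the human table and 297 in the mouse table. Of 650 human gene pairs with start sites within 1000 bp in opposite directions, 59 had at least 1 gene that passed, and 4 had both.

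Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be made afterwards. The test of list means between the cell lines was not among those set down beforehand. The rule names the sorted markers and DHODH, the 10 largest changes each way among genes that passed (5 for the difference and for day 8 against day 6), up to 4 members per list, and the 6 highest and lowest genes of each sublibrary screen (5 for brequinar minus DMSO), and only part of those are printed; some genes are not reported here. Genes of overlaps between screens, ACTL6A in THP-1 and heme, flavin and pyruvate dehydrogenase genes outside that rule were named after their values were seen. Alternatives covered the replicate block, scaling (median of ratios, non-targeting totals), count minimum (none, 100), DESeq2 1.42.0, camera of limma 3.58.1, counts summed per gene, median z, draws from all sgRNAs, start sites as units, no sign rule, each library left out, and a pseudocount of 10. Where a left-out library leaves 1 library in a group, its spread is taken to be that of the other groups.

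The steps were tested on simulated data with 200 changed genes per screen. In the simulated THP-1 screen 83.6% of genes changed by 0.5 on the log2 scale were recovered, and 100% of those changed by 1 or 2, with 13 unchanged genes of 18885 tested passing. In the simulated ER-Hoxa9 CD11b screen the shares were 65.6%, 100% and 100%, with 9 unchanged genes passing of 18994. None of 200 unchanged lists passed in either. Recovery in the data may be lower, since the simulated coefficients of variation, 0.227 and 0.118, lie below the fitted 0.274 and 0.171, and all sgRNAs of a simulated gene act alike. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.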

Results

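The data are sgRNA counts from pooled CRISPR interference screens, in which a catalytically dead Cas9 fused to the KRAB repressor lowers expression of 1 gene per cell and cells are then sorted on a surface protein or a fluorescent reporter. THP-1 is an established human monocytic leukaemia line, K562 an established human erythroleukaemia line, and ER-Hoxa9 a mouse myeloid progenitor line held undifferentiated by estrogen-dependent Hoxa9. CD11b and CD14 are surface proteins of mature myeloid cells, and CD235a is one of red cell precursors. Brequinar inhibits DHODH, the mitochondrial enzyme of pyrimidine synthesis, and lowers nucleotide supply. The 27 libraries fall into 20 groups. THP-1 cells with a genome-wide library received 500 nM brequinar for 48 h and were sorted into the top and bottom 25% of CD11b, in 2 replicates infected separately. ER-Hoxa9 cells received DMSO for 48 h and were sorted at day 8 on CD11b or on GFP, with 2 replicates per fraction, beside 2 unsorted libraries titled day 6. A sublibrary was sorted on CD11b and CD14 in THP-1 with brequinar or DMSO, and on CD235a in K562 with DMSO, giving 10 libraries with 1 per fraction. Plasmid pools gave 3 more libraries.

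Depth differed most among the ER-Hoxa9 libraries, and totals are given in mega-reads (M). THP-1 genome-wide totals were 24.0 and 22.0 M for the CD11b-up fraction and 27.1 and 28.0 M for the down fraction, replicate 1 first, with medians of 89 to 113 reads per sgRNA. ER-Hoxa9 totals were 7.34 and 8.25 M for CD11b high, 3.28 and 6.21 M for CD11b low, 10.7 and 9.52 M for GFP high, 8.83 and 13.3 M for GFP low, and 4.94 and 8.95 M for day 6. Their medians ran from 27 to 111 reads per sgRNA. Sublibrary totals with brequinar were 5.36 and 5.79 M for CD11b high and low and 4.69 and 6.04 M for CD14 high and low. With DMSO they were 4.72 and 3.65 M for CD11b, 7.43 and 5.20 M for CD14 and 7.93 and 8.25 M for K562. The human plasmid pools held 13.4 and 9.22 M and the mouse pool 20.2 M. Below, a log2 ratio is the mean over a gene's sgRNAs of the high fraction over the low one, ± is the SE over those sgRNAs, and n is their number. Genes that "rose" had sgRNAs enriched in the high fraction and genes that "fell" in the low fraction, in both replicates and past the test.

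The first question was which knockdowns change CD11b on THP-1 cells short of pyrimidines. ITGAM, which encodes CD11b, fell by 3.87 ± 0.28 (n = 9; hg38, GENCODE v44, chromosome 16, 31259967 to 31332892). Its 10 sgRNAs together had 117 and 145 reads in the up fraction against 2073 and 2339 in the down fraction. ITGB2, the β-chain that pairs with CD11b at the surface, fell by 2.09 ± 0.39 (n = 10; chromosome 21, 44885953 to 44931989). CD14, which was not sorted on here, had a log2 ratio of 0.08 ± 0.15 and did not pass. DHODH, the target of brequinar, fell by 0.52 ± 0.13 (n = 20; adjusted p = 0.00137, edgeR z against non-targeting sgRNAs, permutation; chromosome 16, 72008588 to 72027664).

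Coactivator genes headed the knockdowns that raised CD11b. SUPT20H rose by 3.86 ± 0.57 (n = 8; chromosome 13, 37009312 to 37059713), KAT2A by 3.32 ± 0.56 (n = 9; chromosome 17, 42113111 to 42121367) and TAF6L by 3.21 ± 0.56 (n = 10; chromosome 11, 62771357 to 62787342). All 3 encode parts of SAGA, a histone acetyltransferase complex, as does TADA1 at 2.47 ± 0.54. KMT2A, the gene rearranged in the MLL-AF9 fusion that THP-1 carries, rose by 3.06 ± 1.03 (n = 9; chromosome 11, 118436456 to 118526832). PSMD4 (2.51 ± 0.44), MTHFD1 (2.48 ± 0.92), SMARCE1 (2.42 ± 0.76), WDR12 (2.19 ± 0.37) and MEAF6 (2.14 ± 0.67) completed the 10 largest increases, although 3 of the sgRNAs of WDR12 are shared with another gene. LEO1 of the PAF1 elongation complex fell most after ITGAM, by 2.82 ± 0.45 (n = 9; chromosome 15, 51938025 to 51971778). ACTR6 (-2.28 ± 0.33), ELOF1 (-2.24 ± 0.52), NCOA6 (-2.14 ± 0.26), DBR1 (-2.10 ± 0.15), KANSL2 (-2.07 ± 0.49), TAF2 (-2.06 ± 0.42) and CUL1 (-2.0 ± 0.37) followed. Each gene of this paragraph reached the smallest adjusted p of the screen, 0.000718, from a permutation p of 1e-05 that is the smallest possible.

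In all, 600 of 18886 genes passed in THP-1, 406 higher and 194 lower. Log2 ratios of the 2 replicates correlated across genes at Pearson's r = 0.546 and Spearman's rho = 0.25, and genes are not independent replicates. Without CD11b-up replicate 2 the count was 364. Of 111 named genes that passed, 84 did so without any 1 library. The SE over sgRNAs does not cover the change between libraries: without 1 library MED12 ran from 1.25 to 3.26, MED23 from 1.12 to 2.17, ELOF1 from -3.79 to -1.60 and CUL1 from -3.41 to -1.73. MCM2, MCM4, TFRC, UTP6, E2F1, MDM4, GART, ADSS and FECH were among the 27 that failed in at least 1 such fit. Of the 600 genes, 50 share sgRNAs with another gene.

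Nucleotide synthesis genes did not move as 1 block in THP-1. Of 6 pyrimidine synthesis genes CTPS1, which makes CTP, rose by 1.24 ± 0.21 and DHODH fell, and the list as a whole was not shifted (permutation adjusted p = 0.209). UCK2, the uridine salvage kinase, fell by 1.00 ± 0.16 and was the only 1 of 12 salvage genes to pass, or 1 higher and 2 lower adjusted over the list alone. Of 12 purine synthesis genes 5 rose, among them ATIC (1.19 ± 0.19) and GART (0.68 ± 0.36), and 6 rose adjusted over the list alone. Of 12 deoxynucleotide supply genes 3 rose, including MTHFD1 and SAMHD1 (1.03 ± 0.37), a dNTP hydrolase. Replication genes rose without exception among those that passed. Of 23 replicative polymerase and clamp loader genes 6 rose, led by POLD3 (1.82 ± 0.50), RFC4 (1.43 ± 0.31) and POLD1 (1.35 ± 0.31), and of 27 origin and CMG helicase genes 6 rose, such as MCM3 (1.23 ± 0.33) and ORC2 (0.99 ± 0.12), 10 adjusted over the list alone. Both lists were shifted upward (permutation adjusted p = 0.000333, from the smallest possible p of 1e-04). In the ATR-CHK1 checkpoint list TIMELESS (0.94 ± 0.27) and RAD17 (0.56 ± 0.19) rose, and each failed in at least 3 of the 4 fits without 1 library. CHEK2 (0.70 ± 0.32, with 2 shared sgRNAs) and MDM4 (0.81 ± 0.19) rose. None of 24 mitosis genes passed.

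By mean z, SAGA and ATAC genes stood highest of the lists in THP-1, followed by ribosome biogenesis, Mediator and SWI/SNF genes. Of 20 SAGA and ATAC genes 9 rose and none fell, 13 adjusted over the list alone, with a mean log2 ratio of 1.09 over the list. Of 18 SWI/SNF genes 9 rose, such as SMARCC1 (1.66 ± 0.43), DPF2 (1.23 ± 0.32) and ARID1A (1.16 ± 0.32), and ACTL6A alone fell. Of 29 Mediator genes 8 rose, 13 adjusted over the list alone, led by MED16 (1.87 ± 0.48), MED12 (1.58 ± 0.16) and MED23 (1.38 ± 0.40). The demethylase gene KDM1A (1.90 ± 0.63) and its partner RCOR1 (1.53 ± 0.61) rose, whereas HDAC1 (-0.91 ± 0.10) and SIN3A (-0.66 ± 0.20) fell, and the corepressor list, with 3 higher and 5 lower adjusted over the list alone, was not shifted (permutation adjusted p = 0.0933). In the list of MLL complexes 3 genes rose and 3 fell, among them MLLT1 (0.98 ± 0.43) and RBBP5 (-0.75 ± 0.17), and 4 each way adjusted over the list alone. Acetyltransferase and BET genes split into 4 higher, including BRPF1 (1.03 ± 0.50) and EP300 (0.96 ± 0.45), and 1 lower, BRD2 (-0.99 ± 0.27), or 4 higher and 4 lower adjusted over the list alone. No PRC2 gene passed over all genes tested. Among 18 myeloid transcription factor genes 5 fell and 2 rose. SPI1, which encodes PU.1, fell by 1.92 ± 0.38 (n = 4) and CEBPD by 1.41 ± 0.16, while IRF8 (1.41 ± 0.19) and CBFB (1.22 ± 0.49) rose. Progenitor factor genes MEF2D (1.14 ± 0.40) and ZMYND8 (1.02 ± 0.25) rose with 2 others of 18, and none fell.

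In the mitochondrial, ribosome and secretory lists a minority of genes passed in THP-1. Of 47 mitochondrial ribosome genes 16 rose and none fell, 26 adjusted over the list alone, such as MRPL10 (1.27 ± 0.26) and MRPL34 (1.23 ± 0.17). Of 35 complex I genes 12 rose, including NDUFS8 (1.43 ± 0.41) and NDUFA9 (1.29 ± 0.31), or 16 higher and 1 lower adjusted over the list alone. Among 27 genes of complexes III to V only COX11 (-0.64 ± 0.20) and ATP5F1 (0.54 ± 0.29) passed, with 1 higher and 4 lower adjusted over the list alone, and both failed in some fits without 1 library. Of 27 ribosome biogenesis genes 10 rose, 18 adjusted over the list alone, with NPM1 (1.43 ± 0.64) and UTP6 (1.37 ± 0.52) beside WDR12. Only 4 of 74 cytosolic ribosomal protein genes rose, for example RPS27 (1.19 ± 0.33), and 4 of 27 splicing genes, for example SF3B3 (1.29 ± 0.20). Heme and iron genes HSCB (1.25 ± 0.31, 2 shared sgRNAs), FDX1L (1.21 ± 0.25), TFRC (1.61 ± 0.34) and FECH (0.64 ± 0.25) rose out of 18. Of 34 N-glycosylation genes 4 fell and none rose, led by DPAGT1 (-1.64 ± 0.36), the first enzyme of the pathway, and ALG14 (-1.17 ± 0.29), and 7 fell adjusted over the list alone. SYVN1 (-0.95 ± 0.18), SEL1L (-0.88 ± 0.14) and CALR (-0.86 ± 0.24) fell among 18 genes of folding and degradation in the endoplasmic reticulum, and the tRNA synthetase genes VARS (-1.23 ± 0.26) and HARS (-1.14 ± 0.40) fell among 26 genes of integrated stress and tRNA charging. No gene of the mTORC1 or RAS-MAPK lists passed. Of 40 lists, 19 were shifted upward and 4 downward by permutation over genes, and all 23 were also shifted against lists matched on mean sgRNA count.

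**Figure D1:**
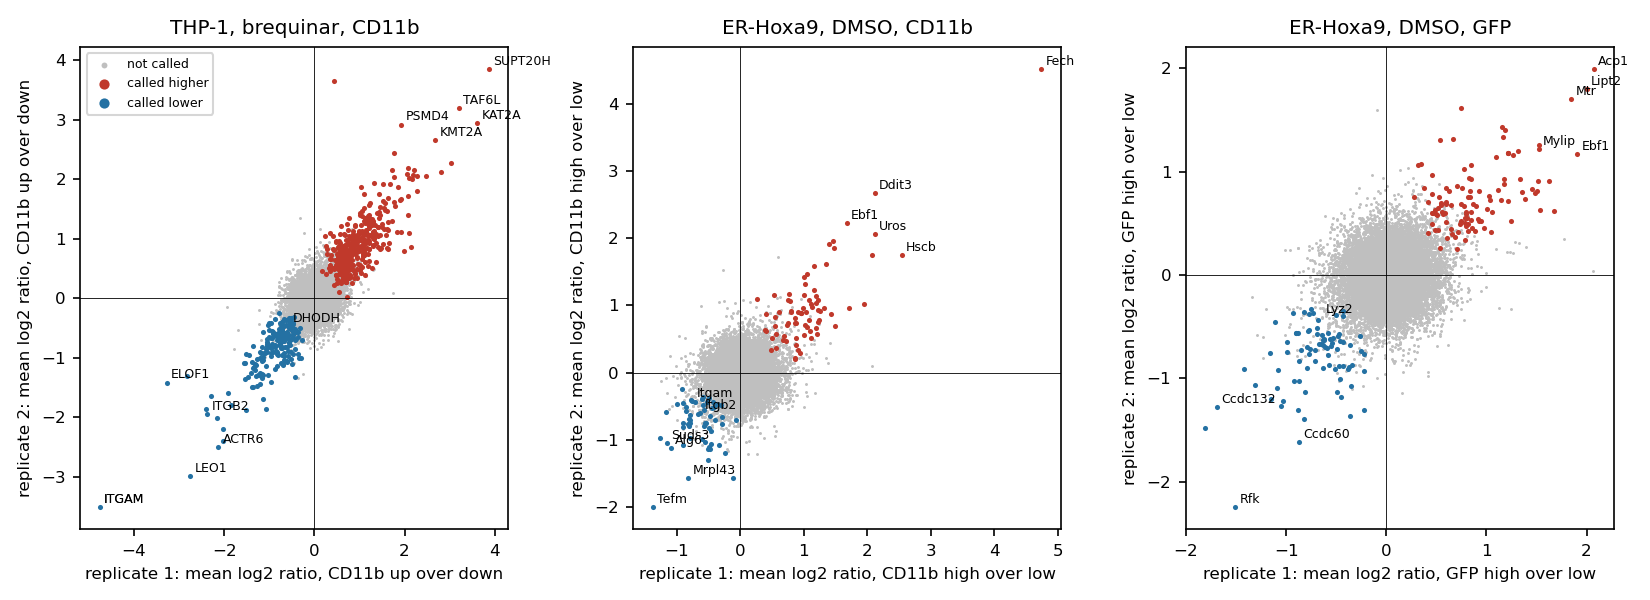
Mean log2 ratio over a gene's sgRNAs in replicate 1 (x axis) and replicate 2 (y axis), computed per replicate with 1 count added, for the 3 sorted genome-wide screens, with 1 point per gene and genes that passed in colour. ITGAM lies lowest on both axes in THP-1, Fech highest on both axes in the ER-Hoxa9 CD11b panel, and Rfk lowest in replicate 2 of the GFP panel.

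The second question was which knockdowns change CD11b on ER-Hoxa9 cells in DMSO at day 8. Itgam fell by 0.62 ± 0.04 (n = 4; adjusted p = 0.0213, edgeR z against non-targeting sgRNAs, permutation), and it failed in all 4 fits without 1 of the CD11b libraries. Itgb2 had a log2 ratio of -0.62 ± 0.23 (n = 5) with an adjusted p of 0.054 by permutation, and with the replicate block its adjusted p was 0.047. Fech, which inserts iron into protoporphyrin in the last step of heme synthesis, rose by 6.12 ± 1.30 (n = 5). Uros, an earlier enzyme of the same pathway, rose by 2.26 ± 1.38 (n = 4), Ppox by 1.17 ± 0.37 (n = 4), and Hscb, a cochaperone of iron-sulfur cluster assembly, by 2.11 ± 0.33 (n = 4). These are the 4 of 14 heme and iron genes that rose, 5 adjusted over the list alone, and none fell. The stress transcription factor gene Ddit3 rose by 2.60 ± 0.49, the B cell factor gene Ebf1 by 2.00 ± 0.52, the SWI/SNF gene Smarcd2 by 1.95 ± 0.46, the methionine synthase gene Mtr by 1.80 ± 0.68 and Kdm1a by 1.57 ± 0.51.

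Mediator genes again lay on the high side in ER-Hoxa9. Of 18 genes 5 rose, among them Med23 (1.89 ± 0.49), Ccnc (1.79 ± 0.39), Med14 (1.16 ± 0.16) and Med1 (1.11 ± 0.38), and none fell, while adjusted over the list alone 7 were higher and 1 lower. Hoxa9 rose by 1.08 ± 0.72 (n = 3), with Max (1.47 ± 0.44), Myc (1.17 ± 0.14) and Myb (0.99 ± 0.33), so 4 of 16 progenitor factor genes rose. Kat2a (1.16 ± 0.24) and 1 other of 17 SAGA and ATAC genes rose, 6 higher and 1 lower adjusted over the list alone. Tfdp1 (1.19 ± 0.21), Ints8 (1.08 ± 0.20) and Men1 (0.87 ± 0.14) rose in the lists of G1/S, Integrator and MLL complexes. None of 13 origin and CMG helicase genes passed over all genes, while 4 were higher adjusted over the list alone and the list was shifted upward (permutation adjusted p = 0.000889). Dhodh had a log2 ratio of 0.57 ± 0.20 (n = 4) and did not pass (adjusted p = 0.105, permutation), and neither did the other 2 pyrimidine synthesis genes measured. That list of 3 was shifted upward (permutation adjusted p = 0.0436), and no longer so without CD11b-low replicate 1 or some other libraries.

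Decreases in the ER-Hoxa9 CD11b screen were smaller than the largest increases. Tefm, an elongation factor of mitochondrial transcription, fell by 1.63 ± 0.37 (n = 3), Mrpl43 by 1.17 ± 0.44, Mrpl44 by 0.96 ± 0.34 and the mitochondrial prolyl-tRNA synthetase gene Pars2 by 0.96 ± 0.47, and each of these 4 failed in at least 1 fit without 1 library. Of 25 mitochondrial ribosome genes 3 fell and none rose, 11 lower adjusted over the list alone, and the mean log2 ratio of the list was -0.44. Timmdc1 (-0.74 ± 0.25) fell in complex I, with 6 lower adjusted over the list alone, and Atp5b (-0.69 ± 0.23) fell in complexes III to V. Of 23 N-glycosylation and translocation genes 5 fell, such as Alg6 (-1.13 ± 0.17) and Ssr2 (-0.83 ± 0.20), and 8 adjusted over the list alone. Other large decreases were Suds3 (-1.11 ± 0.29), Uri1 (-1.06 ± 0.14), Ppa1 (-0.94 ± 0.36), Manf (-0.92 ± 0.16) and Slc31a1 (-0.90 ± 0.41). Lamtor2 (-0.66 ± 0.20) and Rraga (-0.60 ± 0.33) fell among 16 mTORC1 activation genes, of which 3 were higher and 5 lower adjusted over the list alone, and that list was not shifted (permutation adjusted p = 0.603). Tsc1 (-0.60 ± 0.16) fell among 10 mTORC1 inhibition genes.

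In this screen 133 of 18974 genes passed, 76 higher and 57 lower, with a smallest permutation adjusted p of 0.00379 and a Pearson's r of 0.204 between replicates across genes. The count was 74 without CD11b-low replicate 1, 63 without CD11b-high replicate 1 and 31 without CD11b-low replicate 2. Of 49 named genes that passed, 14 did so without any 1 library: Fech, Uros, Hscb, Ddit3, Smarcd2, Med23, Ccnc, Mtr, Max, Kat2a, Tfdp1 and Ints8 on the high side and Alg6 and Suds3 on the low side. Of 40 lists, 12 were shifted upward and 7 downward by permutation, all 19 also against lists matched on count. Without CD11b-low replicate 2, 10 lists were shifted.

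**Figure D2:**
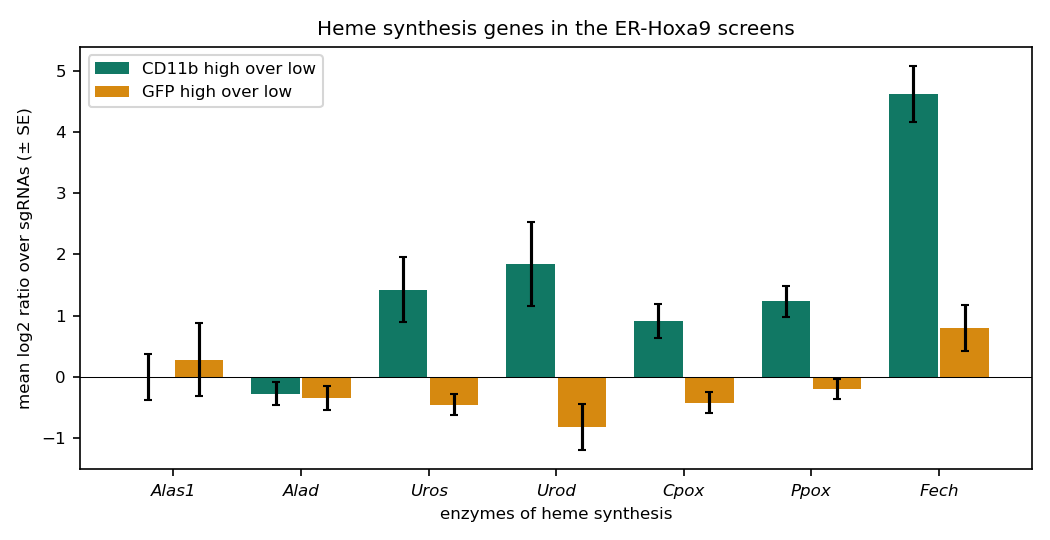
Mean log2 ratio over sgRNAs, ± SE, of 7 heme synthesis genes in the ER-Hoxa9 CD11b (green) and GFP (orange) screens. Ratios were computed per replicate with 1 count added, averaged, and taken with no count minimum, so that values differ from the fitted ones above. Fech stands at 4.63 in the CD11b screen, Uros, Urod, Cpox and Ppox between 0.91 and 1.84, and Alas1 and Alad at -0.00 and -0.28.

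Sorting of the same ER-Hoxa9 cells on GFP asked which knockdowns change the reporter. The identity of the reporter is not given in the sources used here. Lyz2, a mature myeloid gene listed beforehand as a possible reporter locus, had a log2 ratio of -0.51 ± 0.14 (n = 4) and did not pass (permutation adjusted p = 0.138). Itgam stood at 0.01 ± 0.15. The phosphatase gene Acp1 rose most, by 2.06 ± 0.45 (n = 5). Lipt2 (1.85 ± 0.43) and Gcsh (1.33 ± 0.39), which serve protein lipoylation, rose with Mtr (1.82 ± 0.59), Ebf1 (1.58 ± 0.15), Mylip (1.38 ± 0.23), Slc25a1 (1.37 ± 0.22) and Terf1 (1.34 ± 0.59). Hoxa9 (1.29 ± 0.44) and Myb (1.30 ± 0.21) rose as in the CD11b screen. Rfk, which encodes riboflavin kinase, fell most, by 1.99 ± 0.23 (n = 3). Ccdc132 (-1.46 ± 0.22), Ccdc60 (-1.27 ± 0.32), Tkt (-1.26 ± 0.03), Stat3 (-1.19 ± 0.14), Vhl (-1.17 ± 0.37), Tssc1 (-1.16 ± 0.16) and Vps53 (-1.14 ± 0.25) also fell.

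Lists in the GFP screen were shifted downward more often than upward, 11 against 7 of 40 by permutation. Mediator genes lay opposite to their side in the CD11b screen, with Med26 (-0.79 ± 0.29), Med14 (-0.78 ± 0.25) and Med20 (-0.74 ± 0.06, all 5 sgRNAs shared with another gene) lower and none of 18 higher, or 4 lower and 1 higher adjusted over the list alone. Of 6 deoxynucleotide supply genes the folate carrier gene Slc25a32 (-1.10 ± 0.29) and Shmt2 (-0.77 ± 0.19) fell, and the same 2 were the decreases among 6 one-carbon genes. The one-carbon list was not shifted against lists matched on count (permutation adjusted p = 0.0869). Cox5a (-0.73 ± 0.16) fell among 20 genes of complexes III to V, with 9 lower adjusted over the list alone, Ndufb10 (-0.75 ± 0.17) and Ndufa11 (-0.65 ± 0.11) among 35 of complex I, and Mrps16 (-0.80 ± 0.45) among 25 of the mitochondrial ribosome. Pcgf1 (-0.85 ± 0.31) and Rnf2 (-0.56 ± 0.43) of PRC1 fell. Prim2 (0.95 ± 0.31), Pold3 (0.69 ± 0.32), Dbf4 (0.56 ± 0.23) and Kat2a (0.66 ± 0.10) rose in the replication and SAGA lists. Fech rose by 0.72 ± 0.33, although the heme and iron list was not shifted (permutation adjusted p = 0.319).

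Altogether 191 of 18974 genes passed in the GFP screen, 108 higher and 83 lower, at a Pearson's r of 0.218 between replicates. The count was 124 without GFP-low replicate 1, 99 without GFP-high replicate 1, 109 without GFP-low replicate 2 and 120 without GFP-high replicate 2. Of 55 named genes that passed, 21 did so without any 1 library, among them Rfk, Acp1, Lipt2, Gcsh, Mylip, Stat3, Ccdc132, Vps53, Tssc1, Hoxa9 and Myb.

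The difference between the 2 readouts was tested in the same fit as CD11b minus GFP. Fech differed by 5.40 ± 1.25 (n = 5), Rfk by 3.07 ± 0.10 (n = 3), Uros by 2.47 ± 1.46, Ddit3 by 1.97 ± 0.17 and Med23 by 1.94 ± 0.42, all toward CD11b. Toward GFP lay Lipt2 (-2.20 ± 0.61), Acp1 (-1.86 ± 0.37), Ly75 (-1.40 ± 0.45), Gcsh (-1.28 ± 0.32) and Dlat (-1.14 ± 0.37). Of 18 Mediator genes 6 differed toward CD11b, among them Med14 (1.94 ± 0.36), 7 adjusted over the list alone, and 4 of 14 heme and iron genes did, with a list mean of 1.03. Myc (1.67 ± 0.21) and Max differed toward CD11b, whereas Hoxa9 and Myb did not pass. In all 47 genes passed, 31 toward CD11b and 16 toward GFP (edgeR z, permutation), with a smallest adjusted p of 0.00999. The count was 30 without CD11b-low replicate 2, 28 without GFP-low replicate 2, 31 without GFP-high replicate 1 and 31 without GFP-high replicate 2. Of 21 named genes that passed, 12 did so without any 1 library, while Ppox failed in 6 and Ccnc in 4 of 10 such fits. By permutation 7 of 40 lists were shifted, 12 without CD11b-low replicate 2, 3 without GFP-high replicate 2 and 11 without day 6 replicate 1.

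The comparison of day 8 with day 6 asked which sgRNAs were lost or gained late in culture. Its day 8 side is a mean of log2 levels over sorted fractions. An sgRNA strongly skewed to 1 fraction can therefore score low without being lost. The 4 day 8 groups are sorted fractions, and the count table names the earlier libraries day 0 where their titles say day 6, so the interval is uncertain. Pstk, needed for selenocysteine tRNA, fell most, by 2.01 ± 0.17 (n = 3), then Ptplb (-1.72 ± 0.04), Ebf1 (-1.72 ± 0.38), Dicer1 (-1.67 ± 0.67) and Zfp574 (-1.61 ± 0.27). Fech (-1.21 ± 0.36), Ddit3 (-1.18 ± 0.33), Hoxa9 (-1.09 ± 0.24), Mtor (-0.93 ± 0.25) and Mad2l1 (-0.93 ± 0.32) fell as well. SWI/SNF genes such as Smarcc1 (-0.97 ± 0.23) fell in 6 of 16 cases, mitochondrial ribosome genes such as Mrpl4 (-0.68 ± 0.06) in 5 of 25, and integrated stress and tRNA synthetase genes such as Wars (-0.70 ± 0.24) in 4 of 13. The largest increases were small: Vmn2r66 (0.61 ± 0.19), Tas2r117 (0.51 ± 0.18), Gm15127 (0.51 ± 0.26), Pcdhb7 (0.49 ± 0.18) and Lpcat2b (0.48 ± 0.19). In all 432 genes passed, 34 higher and 398 lower (edgeR z, permutation). The count was 278 without day 6 replicate 1 and 140 without day 6 replicate 2. Of 72 named genes that passed, 20 did so without any 1 library, and the 5 increases named all failed without day 6 replicate 2. By permutation 27 lists were shifted downward and none upward, 18 of them also against lists matched on count.

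**Figure D3:**
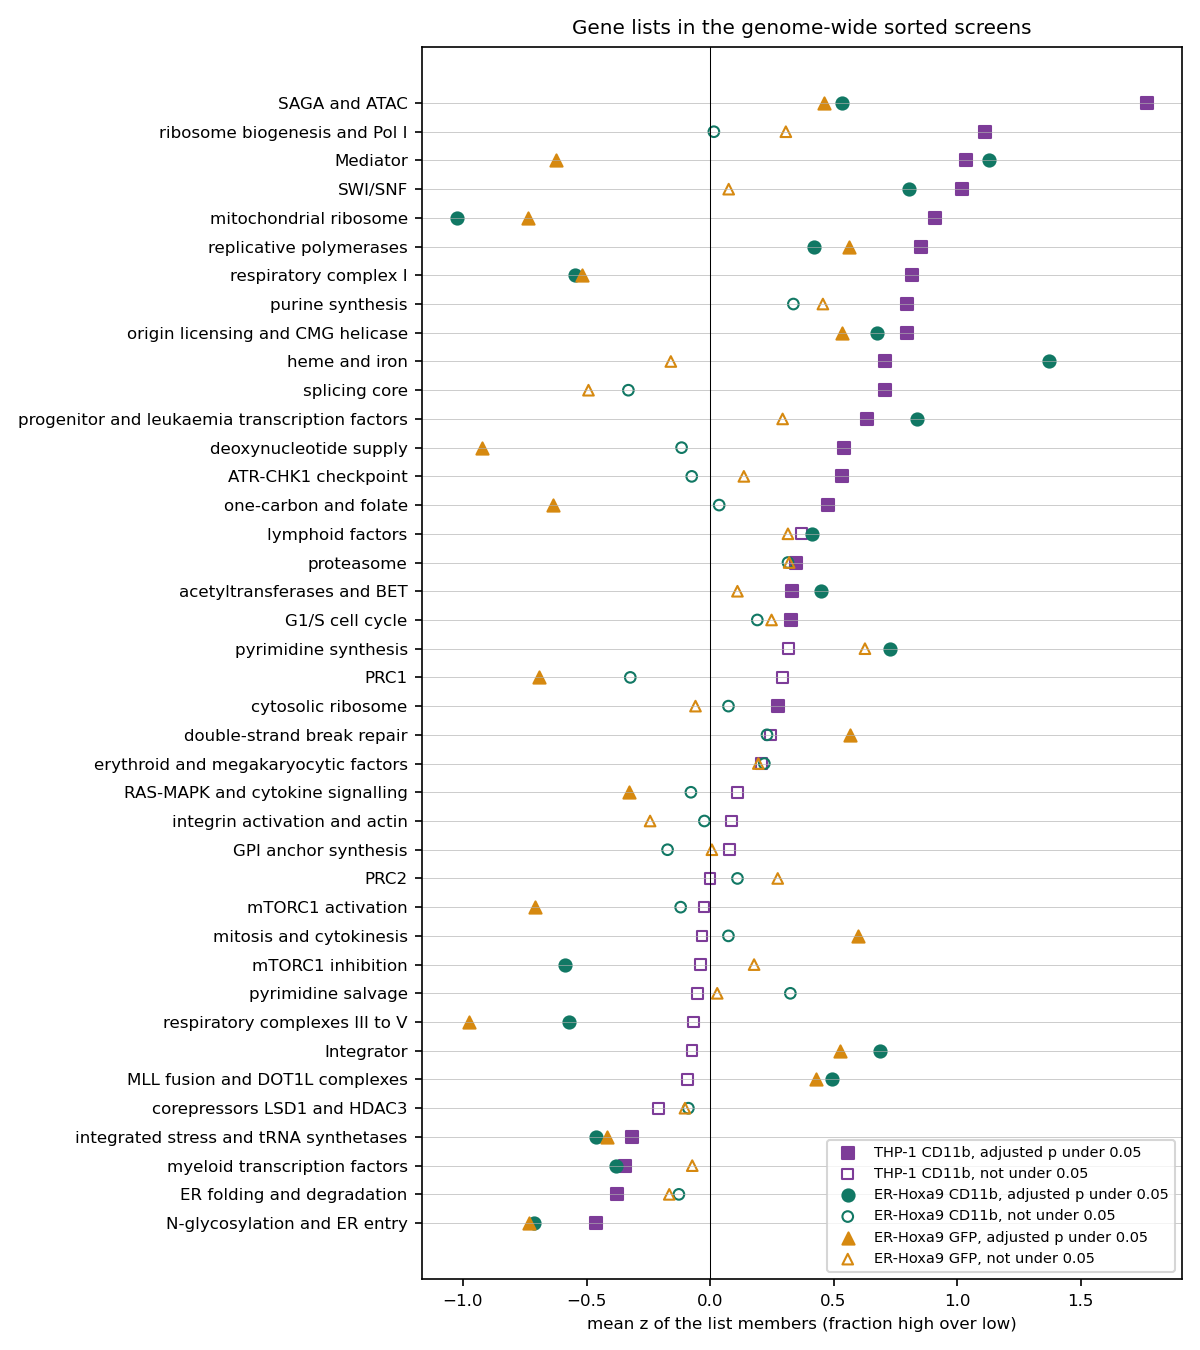
Mean z over the measured members of each of 40 gene lists (x axis) in the THP-1 CD11b, ER-Hoxa9 CD11b and ER-Hoxa9 GFP screens, filled where the permutation adjusted p lies under 0.05. Mitochondrial ribosome and complex I stand right of 0 in THP-1 and left of 0 in both ER-Hoxa9 screens, and Mediator right of 0 in both CD11b screens and left of 0 in the GFP screen.

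Gene statistics of THP-1 and ER-Hoxa9 CD11b screens were nearly uncorrelated across 14635 genes matched by symbol (Spearman's rho = 0.0275, Pearson's r = 0.0892), and genes are not independent replicates. The genes that passed overlapped beyond chance. The same 19 genes rose in both, against 1.28 by chance (Fisher's exact test, p = 1.26e-17), among them KAT2A, KDM1A, MED14, MED23, CCNC, ARID1A, SMARCD2, FECH, HSCB and POLD3. ITGAM, URI1, ACTL6A and 5 others fell in both, 8 against 0.55 by chance (Fisher's exact test, p = 6.53e-08). Over genes with a mean count over 100, with 27 and 6 higher and 16 and 6 lower, none was shared. The counts by chance there were 0.06 and 0.04, so the lack of a shared gene says little about the overlap. MRPL37 and MRPL43 were among 3 genes that rose in THP-1 and fell in ER-Hoxa9, against 1.05 by chance (Fisher's exact test, p = 0.0881). Between the ER-Hoxa9 CD11b and GFP screens Spearman's rho was 0.127 over 18962 genes. HOXA9, MYB, EBF1, MTR and MEN1 were among 33 genes higher in both, against 0.43 by chance (Fisher's exact test, p = 1.13e-55), and 14 such as MANF and SUDS3 were lower in both, against 0.25 by chance (Fisher's exact test, p = 1.98e-21). MED14 and RFK alone rose on CD11b and fell on GFP. Many genes that passed were also lower in ER-Hoxa9 at day 8 than at day 6. On CD11b these were 38 of 76 higher genes (1.6 by chance) and 15 of 57 lower ones (1.2). On GFP they were 39 of 108 (2.27) and 21 of 83 (1.74), and in THP-1 46 of 275 (7.01) and 16 of 143 (3.64). None was higher at day 8. The chance counts of this paragraph do not allow for such shared low values, and the ER-Hoxa9 screens come from the same fit. The day 8 value also averages log2 levels over the same sorted ER-Hoxa9 fractions, and a skew between fractions lowers it. The ER-Hoxa9 overlaps with day 8 may thus follow in part from the design, and are not taken as loss in culture. Between THP-1 CD11b and ER-Hoxa9 GFP, 19 genes rose in both against 1.92 by chance (Fisher's exact test, p = 4.27e-14), and 9, among them CBFB, NDUFA11, NDUFB10 and MRPS16, rose in THP-1 and fell on GFP against 1.48 by chance (Fisher's exact test, p = 1.67e-05).

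The sublibrary screens asked how the knockdown effects depend on brequinar, on the marker and on the cell line. They had 1 library per fraction, so values are described without a test. ITGAM had a log2 ratio of -5.96 ± 0.48 (n = 9) on CD11b with brequinar and -3.37 ± 0.25 with DMSO, and ITGB2 -2.76 ± 0.70 and -1.46 ± 0.31. CD14 stood at -1.19 ± 0.22 and -0.55 ± 0.17 in the CD14 screens. These genes all lay further below 0 with brequinar. Differences between the conditions on the low side were therefore not told apart from a difference between the sorts. DHODH stood at -0.19 ± 0.13 on CD11b with brequinar and 0.46 ± 0.22 with DMSO. PSMD4 was highest on CD11b in both conditions (3.68 and 3.42). With brequinar TAF6L (3.36), SUPT20H (3.14), SMARCE1 (3.06), PDCD11 (2.99) and RCL1 (2.93) came next, and with DMSO NDUFS8 (3.19), GOT2 (3.18), VARS2 (2.97), SMARCE1 (2.95) and FECH (2.84). LEO1 (-2.63), SPI1 (-2.32), NUDCD3 (-2.21) and DPAGT1 (-2.14) were lowest after the integrin genes with brequinar. With DMSO ELOF1 (-1.52), NCOA6 (-1.51) and MBTPS2 (-1.50) were among the lowest after ITGAM, and lay below ITGB2. The largest differences of brequinar minus DMSO on CD11b were GNPNAT1 (-3.10), ITGAM (-2.59), DBR1 (-2.27), COX11 (-2.13) and FECH (-1.95) on the low side, and NOL6 (1.22), PDCD11 (1.16), GINS4 (1.16), PRPF4 (1.09) and WDR12 (1.07) on the high side.

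On CD14, MEAF6 (2.86), MCM2 (2.48), RFC4 (2.37), PSMD4 (2.14), SUPT20H (2.13) and GINS4 (2.12) were highest with brequinar. GOT2 (4.58), CAD (2.99), NDUFS8 (2.98), VARS2 (2.88) and MRPL33 (2.65) were among the highest with DMSO. PDCL was low in both (-1.67 and -1.36), VPS72 (-1.35) and ACTR6 (-1.07) with brequinar, and RFK (-1.50) and MBTPS2 (-1.04) with DMSO. Brequinar minus DMSO was lowest for GOT2 (-2.87), NDUFS8 (-2.74), VARS2 (-2.44), MRPL33 (-2.12) and DBR1 (-2.07) and highest for MEAF6 (1.96), HUS1 (1.14), RFK (0.93), TADA1 (0.88) and SLC35B1 (0.85). In K562, MCM2 (3.23), MED24 (2.55), CCNC (2.53), CAD (2.46), MED16 (2.35) and MED25 (2.29) were highest. KDM1A (-2.40), VARS (-2.36), AARS (-2.08) and COG3 (-1.94) were among the lowest.

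Lists separated the sublibrary screens. The 10 mitochondrial ribosome genes had medians of 0.96 with brequinar and 2.08 with DMSO on CD11b, 0.16 and 1.68 on CD14, and -0.51 in K562, where none of the 10 lay above 0. The 9 complex I genes gave 1.24 and 1.51 on CD11b, 0.23 and 1.26 on CD14 and -0.03 in K562. SAGA and ATAC genes (11) ran the other way between conditions, at 1.43 with brequinar and 1.06 with DMSO on CD11b and 0.89 and 0.46 on CD14, and at -0.32 in K562 with 1 of 11 above 0. Mediator genes (8) had their highest median in K562 (2.14) and stood at 1.40 and 1.67 on CD11b and at 0.25 and 0.69 on CD14. Replicative polymerase genes (8) lay between 1.55 and 1.74 in all 5 screens, and pyrimidine synthesis genes (4) between 1.01 and 1.57, while genome-wide the median over all 6 was 0.12 in THP-1. The 7 N-glycosylation genes stood at -0.74 with brequinar and -0.19 with DMSO on CD11b, and above 0 at 0.31 and 0.27 on CD14 and 0.12 in K562. Across 1569 genes, which are not independent replicates, brequinar and DMSO correlated at a Spearman's rho of 0.698 on CD11b and 0.469 on CD14, and K562 with the THP-1 screens at 0.0879 to 0.161. Of the 600 genes that passed genome-wide, 449 are in the sublibrary, and 441 kept their sign on CD11b with brequinar, 402 with DMSO and 238 in K562. On CD14 338 did with brequinar and 306 with DMSO. Of 177 genes that had fallen, 170 with brequinar and 132 with DMSO kept their sign on CD11b, and 95 and 62 on CD14. Of 272 that had risen, 271 and 270 did on CD11b, and 243 and 244 on CD14. How the sublibrary's genes were chosen is not given in the sources used here, so these medians and counts are not taken as independent of the genome-wide screen.

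**Figure D4:**
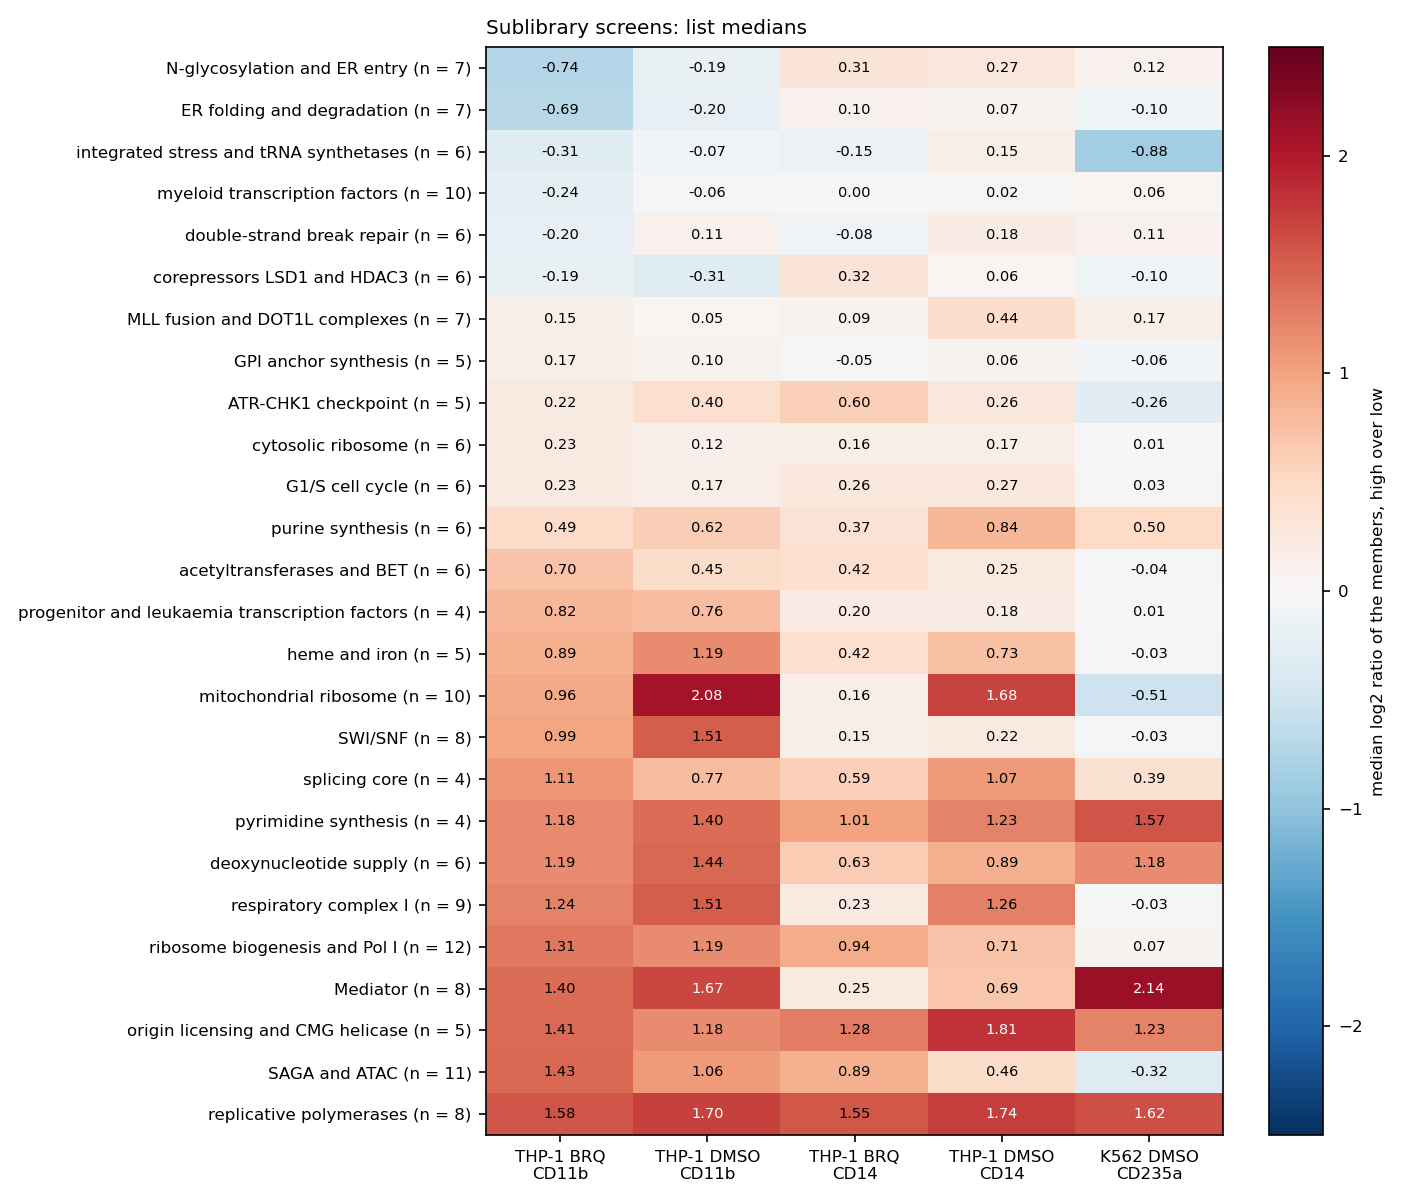
Median log2 ratio (high over low fraction, colour and printed number) of the measured members of each gene list with at least 4 members in the 5 sublibrary screens, 1 library per fraction. Mitochondrial ribosome genes run from 2.08 on CD11b with DMSO to -0.51 in K562, and replicative polymerase genes stay between 1.55 and 1.74.

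Cells were also set against the plasmid pools, with 1 library per pool and no test. The THP-1 side was the mean of the 4 sorted libraries with brequinar. The ER-Hoxa9 side was the mean of the 2 unsorted libraries titled day 6. Genes had a median of 10 human or 5 mouse sgRNAs, and the SD of non-targeting sgRNAs was 0.58 and 0.87. Differences between the 2 sets of values are therefore not taken as differences between the cell lines. Proteasome genes had the lowest human list median, -1.70, with mitosis genes at -1.40, splicing genes at -1.29 and cytosolic ribosome genes at -1.08. In ER-Hoxa9 mitosis genes stood at -2.91, splicing genes at -2.79, proteasome genes at -2.68 and cytosolic ribosome genes at -2.13. Mitochondrial ribosome genes had medians of -0.08 in THP-1 and -1.03 in ER-Hoxa9, purine synthesis genes -0.13 and -1.37, and deoxynucleotide supply genes -0.34 and -2.04. Of 18828 human genes 465 lay below -1, and 1586 of 20001 mouse genes did. Human and mouse values correlated at a Spearman's rho of 0.225 across 15556 genes, which are not independent replicates.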

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

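The lists were fixed beforehand, but their test between the cell lines was not among the tests set down then. The tests of explanations for the mitochondrial lists were chosen after their values were seen. THP-1 cells had brequinar and ER-Hoxa9 cells DMSO, so cell line, species, time in culture and treatment differ together. Values are mean scaled z over genes measured in both CD11b screens, THP-1 minus ER-Hoxa9, with permutation adjusted p over 40 lists.

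Knockdown of mitochondrial ribosome genes went with high CD11b in THP-1 and low CD11b in ER-Hoxa9, at 1.76 against -1.86 over 25 genes, a difference of 3.62 (permutation adjusted p = 0.001, the smallest reached). Complex I genes differed by 2.72 (1.73 against -0.992 over 35 genes; permutation adjusted p = 0.001). MRPL43 and MRPL37 passed in both screens with opposite signs, but in ER-Hoxa9 Mrpl37 failed in 3 and Mrpl43 in 2 fits without 1 library.

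The tables argue against 2 technical causes of this opposition. In this paragraph ± is the SE over genes, which are not independent replicates. If the count minimum had removed members with another sign in ER-Hoxa9, the mean over all 82 members without a minimum would lie at or above 0, and it was -0.39 ± 0.05. Without the shallowest library, CD11b-low replicate 1, the mean over 63 members was -0.39 ± 0.04. Brequinar as the cause could not be settled. In THP-1 with DMSO the 19 members in the sublibrary averaged 1.63 ± 0.19 on CD11b and all 19 lay above 0, against -0.25 ± 0.12 for 14 of them in ER-Hoxa9, but the sublibrary holds a chosen 19 of 82 members with 1 library per fraction. A difference between the cell lines, of species, lineage stage or nutrient supply, may account for the opposition, and stays untested.

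The other lists that differed are given as values. Pyrimidine synthesis differed by -2.79 over 3 genes, DHODH among them, at -1.47 in THP-1 and 1.32 in ER-Hoxa9 (permutation adjusted p = 0.012), while over all 6 members the THP-1 mean z was positive, at 0.318, and the list was not shifted. SAGA and ATAC differed by 2.8, at 3.77 and 0.969 (permutation adjusted p = 0.001). Ribosome biogenesis differed by 2.51 over 12 of 27 genes, at 2.54 and 0.0279 (permutation adjusted p = 0.001). The splicing core differed by 2.14 over 6 of 27 genes (permutation adjusted p = 0.0104). The other members of both lists fell to the count minimum in ER-Hoxa9, where the list medians against the plasmid pool were -1.57 and -2.79. No mean without a count minimum was computed for the lists of this paragraph. Dropout of members is thus not told apart from a difference of the cell lines. Heme and iron genes differed by -0.96, at 1.53 and 2.49 (permutation adjusted p = 0.0215). Integrator genes differed by -1.27 (permutation adjusted p = 0.0215), PRC1 genes by 1.21 (permutation adjusted p = 0.0316) and ATR-CHK1 checkpoint genes by 1.28 (permutation adjusted p = 0.0472).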

How the results depend on the processing

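Leaving out each library for the gene lists, leaving out genes with shared sgRNAs and leaving out sgRNAs with empty cells were chosen after seeing the data. For named genes there were 8216 values over 408 results. Of these, 7416 stayed on their side of the threshold, 769 were no longer past it and 31 newly past it. No named gene that had passed did so with the opposite sign in another fit, while changes of sign short of the threshold were not counted. Of 2160 list values 2037 stayed, and of 375 sublibrary gene values all stayed within the spread over sgRNAs. The replicate block ended 5 calls of named genes (among them Aars and Tada3 on GFP, Dpm3 at day 8 and PRPF6 in THP-1), made 1 (Itgb2), and changed no other call of a named gene or list. With the block 635 genes passed in THP-1 (589 of the 600 kept), 140 on ER-Hoxa9 CD11b (131 of 133) and 190 on GFP (183 of 191). For the difference 46 passed (45 of 47), and for day 8 453 did (425 of 432). Scaling alternatives moved no count by more than 1.5 times. A mean count of at least 100, which by construction tests fewer sgRNAs, gave 289 genes in THP-1 (257 of the 600 kept), 11 on ER-Hoxa9 CD11b (11 of 133), 26 on GFP (22 of 191), 6 for the difference (5 of 47) and 13 for day 8 (13 of 432). No count minimum gave 1419 for day 8. Draws from all sgRNAs gave 50 on ER-Hoxa9 CD11b, 111 on GFP and 126 for day 8. Median z gave 69 on ER-Hoxa9 CD11b, 28 for the difference and 262 for day 8, and camera with its preset correlation 224 for day 8; an estimated correlation was not run. The cause of these changes was not tested. Without 1 library the counts ran from 364 to about 5.6e2 in THP-1, 31 to 146 on ER-Hoxa9 CD11b, 99 to 193 on GFP, 28 to 50 for the difference and 140 to 451 for day 8, and the lists shifted from 10 to 20 on ER-Hoxa9 CD11b and from 3 to 12 for the difference. Over genes with a mean count over 100 Spearman's rho was -0.0048 between the THP-1 and ER-Hoxa9 CD11b screens, which reverses the sign of 0.0275, and 0.0947 between ER-Hoxa9 CD11b and GFP. It was 0.4165 between CD11b and CD14 with brequinar, 0.4006 between CD11b with DMSO and CD14 with brequinar, and 0.3953 between CD11b and CD14 with DMSO. K562 with THP-1 CD11b went from 0.1025 to 0.0539 with brequinar and from 0.0879 to 0.0488 with DMSO, each inside the 95% interval of the first value. The cause was not tested. No second table of the same libraries was used, so that alternative was not run. The ER-Hoxa9 libraries had medians of 27 to 111 reads per sgRNA.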

Other observations

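All tests in this part were chosen after the values were seen, and their gene sets were put together afterwards. Late heme synthesis genes had log2 ratios above 0 in ER-Hoxa9 cells sorted on CD11b. Fech, Uros and Ppox were among the genes that passed in that screen, and Urod and Cpox were not. Without a count minimum, sgRNAs against the enzymes that act on porphyrins or their precursors lay on the high side, with Fech at 4.63 ± 0.45, Urod at 1.84 ± 0.69, Uros at 1.42 ± 0.53, Ppox at 1.23 ± 0.25 and Cpox at 0.91 ± 0.28. Alas1 (-0.00 ± 0.38, mean count 14) and Alad (-0.28 ± 0.19), which act before that point, were not above 0. On GFP the same late genes other than Fech lay below 0, from -0.20 for Ppox to -0.82 for Urod. In the THP-1 sublibrary with DMSO, FECH stood at 2.84 ± 0.72 on CD11b and 1.34 ± 0.31 on CD14. With brequinar FECH stood at 0.89 ± 0.35 and 0.003 ± 0.078. These values have 1 library per fraction, and the dyes are not given in the sources used here, so they decide no explanation.

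Flavin and lipoate genes lay on opposite sides of the GFP screen. The flavin genes Rfk (-1.99), Slc25a32 (-1.10), Flad1 (-0.91) and Slc52a2 (-0.64) all fell. The pyruvate dehydrogenase, lipoylation and pyruvate carrier genes Lipt2 (1.85), Gcsh (1.33), Dlat (1.24), Pdha1 (1.12), Lipt1 (0.79), Pdhb (0.62) and Mpc1 (0.61) rose, while Lias, Dld, Pdhx and Mpc2 did not pass.

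For the heme genes, a candidate explanation is light from accumulated porphyrins read in the CD11b channel, since loss of the late enzymes leaves such precursors. The 5 late genes averaged 2.15 above Alas1 and Alad (2.01 against -0.14). The p was 0.190 in a two-sided exact permutation over 21 splits, on a gene set made smaller after a first run. All 5 lay above both early genes, so no split gave a larger difference in that direction. The splits with a larger absolute difference set Fech among the early genes, so with these values the test could not pass. As first worded, a p of 0.05 or more would have counted against this explanation; the bound was changed to a lower mean of the late genes after the p was seen, because a p that misses the threshold does not show equal values, and the explanation is left open. For counting noise, the highest of 10000 draws of count-matched non-targeting sgRNAs was 0.39, where the 30 late sgRNAs averaged 1.91 ± 0.32. The set was put together after some of its genes were seen to be high in this screen. The draws thus show only what unselected sgRNAs of such counts reach, and do not decide the question. For loss of heme itself raising CD11b, Alad, the only early gene with enough reads and as strong a loss from the culture (-1.05 against -0.93), goes against it at -0.28 ± 0.19, but 1 gene does not settle it.

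For the GFP genes, a shift of differentiation seen by both readouts was examined by the signed mean over 15 genes, with ± as the SE over genes. It was -0.025 ± 0.0906 on CD11b, so no shift of the set was seen there, and 0.888 ± 0.143 on GFP. The genes and their signs were chosen after the GFP values were seen, which by itself raises the GFP mean. The gap between the readouts therefore does not decide the question. Green autofluorescence of flavins is a candidate explanation that the data leave open. RFK stood at -1.50 ± 0.20 on CD14 and 0.14 ± 0.16 on CD11b in THP-1 with DMSO. With brequinar RFK stood at -0.57 ± 0.17 on CD14. No GFP is named for these THP-1 cells, but the dyes of those stains are not given in the sources used here. An effect of these pathways on the reporter's own expression was not tested.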
